A study of Rattus norvegicus with 18 samples.

How the data were processed

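Levels were read from the deposited transcript assemblies of 18 libraries, and per the file headers the unit of each transcript was TPM, beside FPKM and mean coverage. TPM of the transcripts of a gene was summed, giving 17337 genes, named by the symbols of the files. Coordinates are those of the files, on rn6. A table of a later assembly was used for names only: 14821 gene names were its symbols and 2125 more its synonyms.

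The submitters' processing notes name Trimmomatic, HISAT2 and Bowtie without role, order or version. Per the file headers quantification was done with StringTie 1.3.2d against a UCSC annotation. Quantification was limited to annotated transcripts and no strand option was given, although the kit was stranded, so overlapping genes on opposite strands cannot be told apart. The library kit was made for picogram inputs of total RNA, and sequencing was in pairs of 150 bases. The growth text is repeated for all samples, so the uncultured libraries are called primary sorted. Names in the file headers differ from the numbers in the titles, so numbers were not taken to pair samples.

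Exonic bases were estimated from coverage times transcript length, and read pairs from them at 300 bases per pair. Aligned bases were estimated from the ratio of coverage to FPKM of covered transcripts. Aligned bases had a median of 24.2 megabases per library, and pairs outside ribosomal RNA a median of 41657. TPM was divided by median-of-ratios factors from 1644 genes above 0 in all libraries. Genes with a TPM of at least 1 in at least 3 libraries were tested, 15144 in all. Values of log2(scaled TPM + 1) were fitted with 6 group means in limma 3.58.1 under R 4.3.3 with statmod 1.5.0, with a trend in the variance, and p was adjusted by Benjamini and Hochberg with a threshold of 0.05. The 6 groups shared 1 estimate of the spread per gene. Culture comparisons set the mean of both gels against primary cells. Of 35 gene lists written beforehand 34 were tested with camera at a preset correlation of 0.01, beside an estimated correlation; mitochondrially encoded genes had 0 members in the files and were not analysed here.

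Genes were named by a rule fixed beforehand: per comparison the 8 called genes with the largest rise and the 8 with the largest fall, at a mean TPM of at least 5 in the higher group and without overlap between groups, up to 4 members of each called list, and always Pdgfra, Mbp, Mki67 and Piezo1. The comparisons, the lists, the test, the filter, the named-gene rule and the first set of alternatives were chosen before the data were examined. Those alternatives were a pseudocount of 0.1, no filter, a TPM filter of 5, no scaling, quantile normalization, voom on read equivalents, array weights, robust variances, only the groups compared, a replicate block, and each library left out in turn. A further run with newly assembled transcripts was not run, because the files hold annotated transcripts alone. After the data were seen 3 alternatives were added: the 3 broad libraries left out, libraries thinned to 22193 pairs, and the olfactory receptor level as a covariate. The thinned alternative was first run without the TPM filter and then with it.

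Recovery was tested by simulation, whose design was revised 2 times after its recovery was seen, first by separating genes by their mean pairs and then by adding a fold of 64. For genes of 5 to 100 mean pairs limma recovered 0%, 0%, 20%, 35% and 75% at folds of 2, 4, 8, 16 and 64, and for genes of 1 to 5 pairs 0%, 0%, 5%, 10% and 45%. Recovery differed by direction: at a fold of 64 it was 100% of genes raised and 50% of genes lowered at 5 to 100 pairs, and 90% and 0% at 1 to 5 pairs, so splits into higher and lower genes are affected. In the same simulation voom recovered 0%, 5%, 60%, 70% and 90% at 5 to 100 pairs and 0%, 0%, 40%, 45% and 55% at 1 to 5 pairs, with more false calls. Unchanged genes made up 3 of the calls by limma on log2 values, or 7.32%, against 30 calls or 29.1% by voom, and 0 of 20 random lists were called. Each gene was drawn independently at a dispersion of 0.3, around a mean share of reads common to all libraries unless changed. No simulated library was broad. Random lists were therefore unlikely to be called, and false calls in the real libraries may be more frequent. Coordinates are not printed for genes with several loci. One gene that the naming rule selected is not reported here.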

Results

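Oligodendrocyte progenitor cells (OPCs) are the glial cells of the central nervous system that divide and form myelinating oligodendrocytes. Total RNA was sequenced from rat OPCs enriched with magnetic beads, from aged and from neonate animals, in 6 groups of 3 libraries. Primary sorted cells made up 2 groups, aged and neonate. The other 4 held aged or neonate cells grown on laminin-coated hydrogels that the labels call soft or stiff. The ages of the primary sorted libraries are given only by a letter in each title. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Levels are in TPM, the length-corrected share of transcripts, divided by a scaling factor per library and called scaled TPM, and genes carry the symbols of the files with rn6 coordinates.

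Depth was low in every library. Aligned bases came to 12.9 to 52.6 megabases per library, and those on annotated exons to 33939 to 141883 read pairs if each pair covers 300 bases. Ribosomal RNA took 44.5% to 88.8% of the TPM. Without it, 22200 to 105647 pairs remained, so that 1 read pair on a transcript of 2 kb was worth 3.16 to 14.3 TPM. Genes with any coverage numbered 5842 (aged stiff replicate 3) to 14999 (aged primary replicate 1) of 17337. Among the values tested 41.4% were 0, and 7 of 15 housekeeping genes were listed at 0 in at least 1 library, so a value of 0 does not show that a gene was silent. Levels of genes that reach 0 in a compared library are therefore given per library, in the order of the replicates.

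The libraries also differed in how widely reads were spread. Replicate 1 of each aged group detected more genes than any other library after all were thinned to 22193 pairs, with 8571 to 9416 genes against 4770 to 7697. Olfactory receptor genes, which belong to sensory neurons of the nose, were covered at 77.2% of 1197 in aged primary replicate 1, 66.9% in aged soft replicate 1 and 54.7% in aged stiff replicate 1. Aged soft replicates 2 and 3 followed with 39.2% and 30.8%. In the other 13 libraries the share was between 0.251% and 18.9%. These 3 replicate 1 libraries are called the broad libraries here, and each count of called genes was also made without them, an alternative chosen after the data were seen.

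**Figure D1:**
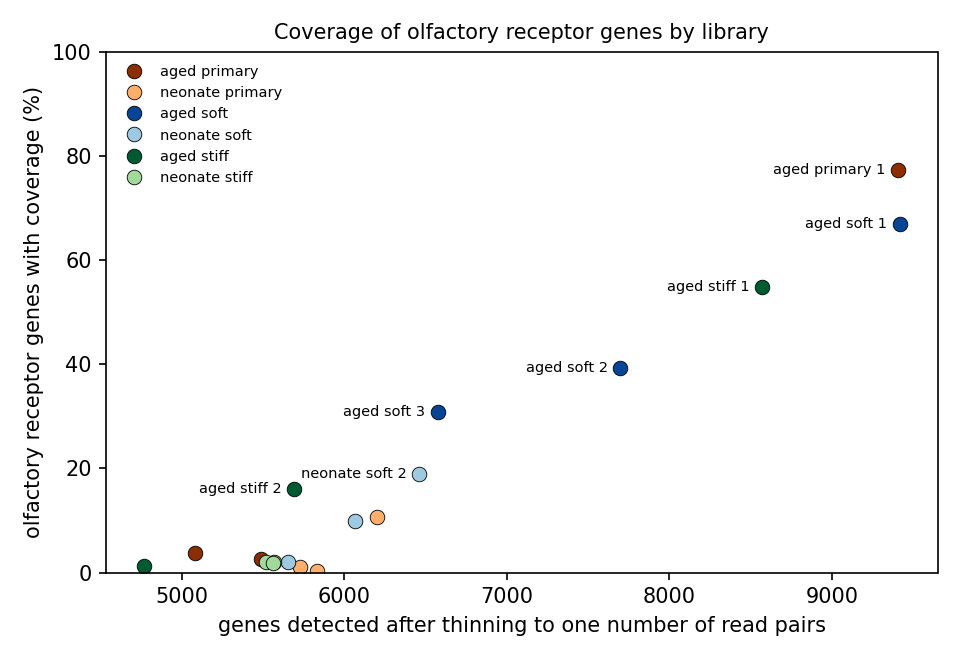
Each point is 1 library. The horizontal axis gives the genes detected after thinning to 22193 read pairs and the vertical axis the percentage of 1197 olfactory receptor genes with coverage; the 3 broad libraries lie at 54.7% or more.

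The comparison of aged with neonate primary sorted cells asks how the transcriptome of OPCs differs with age. Aged libraries had higher levels of genes of microglia, lysosomes and antigen presentation, and lower levels of OPC genes. C3, complement component 3 (chromosome 9, 9721137 to 9747084), was at 239, 364 and 301 scaled TPM in the aged libraries and 0.249, 0 and 0 in the neonate ones (limma, adjusted p = 2.4e-06). Pdgfra, the growth factor receptor that marks OPCs (chromosome 14, 35527926 to 35581031), fell from 53.7, 42.6 and 74.7 in neonate to 15.9, 0 and 0 in aged libraries (limma, adjusted p = 0.00595). In all, limma called 394 of 15144 genes, 294 higher and 100 lower in aged cells, against a median difference of all genes of 0.69 on the log2(scaled TPM + 1) scale.

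Of the 20 microglia genes, 17 rose in aged primary cells, and 20 when adjusted over the list alone. Their median difference relative to that of all genes was 4.01 (camera, adjusted p = 9.14e-25, or adjusted p = 2.41e-05 with an estimated correlation). Tmem119, a marker of resident microglia (chromosome 12, 48598647 to 48605704), was at 39.3, 79.8 and 182 in aged libraries and listed at 0 in neonate libraries (limma, adjusted p = 0.00131). The myeloid transcription factor Irf8 (chromosome 19, 54318463 to 54335105) was at 222, 371 and 277 against 0, 0 and 13.2 (limma, adjusted p = 8.26e-05). Other large rises were those of Lat2, an adaptor of immune receptor signalling, Cxcr5, a chemokine receptor, Selplg, a selectin ligand, the niacin receptor Niacr1, the phosphatase Ppm1n, and Mir3555, which overlaps Mir191 on the opposite strand.

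Lysosome genes rose in 8 of 30 cases (15 adjusted over the list alone) and MHC and antigen processing genes in 4 of 18 (11 adjusted over the list alone). Both lists were called by camera (adjusted p = 1.15e-10 and 1.33e-09), with adjusted p = 0.00407 and 0.00163 with an estimated correlation. Npc2, which carries cholesterol out of lysosomes (chromosome 6, 108467410 to 108488330), was 903 ± 379 scaled TPM (SD, n = 3) in aged and 32.3 ± 23.9 in neonate libraries (limma, adjusted p = 8.52e-05). Cd74, the MHC class II invariant chain, was at 218, 549 and 229.6 against 2.57, 0 and 7.55 (limma, adjusted p = 0.000311). The interferon list (3 of 28 rose, 6 adjusted over the list alone; B2m, Usp18 and Ifi27) was called at adjusted p = 0.000108 and lost that call at adjusted p = 0.0879 with an estimated correlation. The heat shock and unfolded protein list (2 of 28 rose, 6 adjusted over the list alone; the near-identical pair Hspa1a and Hspa1b, whose reads cannot be told apart with certainty) went the same way, at adjusted p = 0.00255 and adjusted p = 0.139 with an estimated correlation.

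Of the 19 OPC genes, 5 fell in aged primary cells (11 adjusted over the list alone), with a median relative to all genes of -3.20 (camera, adjusted p = 7.66e-19, or adjusted p = 0.00163 with an estimated correlation). Ncan, a brain proteoglycan (chromosome 16, 21050243 to 21076707), fell from 214, 147 and 200.4 scaled TPM in neonate to 14.9, 4.64 and 0 in aged libraries (limma, adjusted p = 0.000312). Olig1, a transcription factor of the oligodendrocyte lineage (chromosome 11, 31428377 to 31430519), fell from 315 ± 61.6 to 23.9 ± 30.8 (SD, n = 3; limma, adjusted p = 0.00191), and Sox6 fell from 23.8, 32.9 and 18.3 to 2.35, 0 and 0 (limma, adjusted p = 0.0257). The mature oligodendrocyte list was higher as a whole (4 of 20 rose and 1 fell, 14 and 1 adjusted over the list alone; camera, adjusted p = 7.78e-07, or adjusted p = 0.0343 with an estimated correlation). Its risers included Tf, the iron carrier transferrin, Ptgds, prostaglandin D synthase, and Aspa, an aspartoacylase, while Mog, a myelin surface protein whose gene overlaps Zfp57 on the opposite strand, fell from 316, 168 and 229 to 16.9, 0 and 23.5 (limma, adjusted p = 0.000927). Mbp, the myelin basic protein, was at 54, 27.5 and 85.1 in aged and 6.38, 21.6 and 0 in neonate libraries and was not called (limma, adjusted p = 0.11). Lims2, an adhesion adaptor in the list of committed oligodendrocyte genes, fell from 394 ± 34.5 to 4.91 ± 3.25 (SD, n = 3; limma, adjusted p = 5.47e-05). Its gene overlaps Gpr17 on the other strand, and counting without strand cannot separate the pair.

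S phase genes had a median of -1.71 relative to all genes in aged primary cells (2 of 26 fell, also 2 adjusted over the list alone; camera, adjusted p = 4.1e-07, or adjusted p = 0.0879 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase (chromosome 6, 43884627 to 43890818), fell from 173, 299.6 and 280.0 to 12.7, 0 and 0 scaled TPM (limma, adjusted p = 5.05e-05), and Gins2, of the replicative helicase, fell from 616 ± 80.3 to 106 ± 32.9 (SD, n = 3; limma, adjusted p = 0.00393). Mki67, a marker of dividing cells, was 31.4 ± 17.4 in aged and 7.1 ± 2.61 in neonate libraries (SD, n = 3; limma, adjusted p = 0.326). The G2 and M phase list was called lower with 0 members called (0 adjusted over the list alone; camera, adjusted p = 5.7e-05, or adjusted p = 0.189 with an estimated correlation). Further falls were those of the histone gene Hist1h2bd, the growth factor Ptn, Pmch, Ngfrap1, and Mir3597-1 and Mir3597-2, which overlap Mir9-1 and Mir9-2 on the other strand. Values of these Mir3597 entries are not shown to be microRNA levels.

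Ptn, Pmch and Ngfrap1 were listed at 0 in all 3 aged primary libraries. In all, camera called 22 of 34 lists in this comparison, of which 5 (microglia, OPC, lysosome, MHC and mature oligodendrocyte) were also called with an estimated correlation. Neuron genes were among those lower (2 of 16 fell, Dcx and Stmn2, 3 adjusted over the list alone; camera, adjusted p = 0.000429, or adjusted p = 0.189 with an estimated correlation), and so were astrocyte genes (0 of 16 fell, 0 adjusted over the list alone; adjusted p = 0.00396, or adjusted p = 0.191 with an estimated correlation). Endothelial genes were called higher (0 of 15 rose, 1 adjusted over the list alone; adjusted p = 0.0386, or adjusted p = 0.535 with an estimated correlation). For committed oligodendrocyte genes the test was negative (adjusted p = 0.0226, or adjusted p = 0.358 with an estimated correlation), the mean was -0.19 and the median 0.66. The endothelial call was lost without the 3 broad libraries, after thinning and with the olfactory covariate (camera, adjusted p = 0.380, 0.0685 and 0.150), as was that of committed oligodendrocyte genes (adjusted p = 0.153, 0.0714 and 0.294). The astrocyte call was lost without the broad libraries (adjusted p = 0.0648). Without the 3 broad libraries 500 genes were called, 326 of them shared with the 394, but fewer lists. The count was 160 genes with a pseudocount of 0.1 and 971 by voom, and lower than 160 with only the groups compared. With no scaling the split was 241 higher and 154 lower, and with quantile normalization 234 and 221. Leaving out 1 library gave 166 (without aged replicate 2), 169 (aged replicate 3), 203 (neonate replicate 1), 180 (neonate replicate 2) or 194 genes (neonate replicate 3), and 13 lists without aged replicate 1. Of 45 named calls 33 held whichever library was left out, and those of Aspa, Cyfip2, Dcx, Enpp6, Fau, Hspa1a, Ifi27, Mir3597-1, Pdgfra, Pmch, Sox6 and Stmn2 did not.

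**Figure D2:**
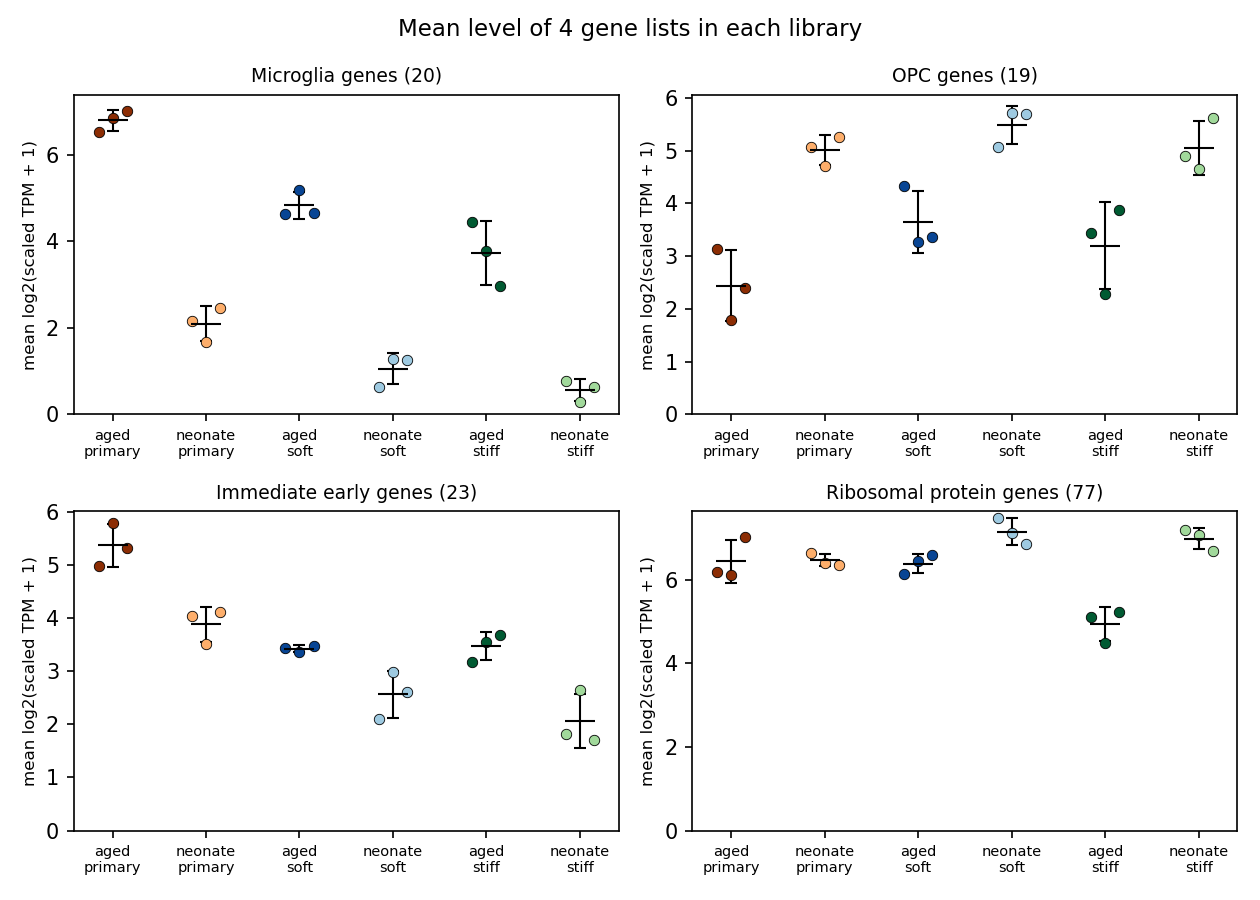
Each panel shows the mean log2(scaled TPM + 1) over the genes of 1 list in each of the 18 libraries; points are libraries, and bars give the mean and SD of 3 libraries per group. Microglia genes average 6.80 in aged primary and 2.10 in neonate primary libraries, and ribosomal protein genes 4.94 in the aged stiff group.

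The comparison of soft with stiff gels in aged cells asks whether the stiffness of the surface alters the transcriptome of aged OPCs. Ribosomal protein genes were higher on soft than on stiff gels as a list in the preset test (camera, adjusted p = 4.92e-08), but not at adjusted p = 0.215 with an estimated correlation. Rpl27, a protein of the large ribosomal subunit (chromosome 10, 89353129 to 89356563), rose from 185 ± 64 scaled TPM on stiff to 716 ± 69.1 on soft gels (SD, n = 3; limma, adjusted p = 0.0382). In all 12 genes were called, each of them higher on soft gels, and the median difference of all genes was 0.59. Dctn6, a subunit of dynactin (chromosome 16, 61795544 to 61814734), was at 32.4, 31.2 and 29.5 on soft gels and listed at 0 on stiff gels in all 3 libraries (limma, adjusted p = 0.00452).

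The other genes called on soft gels in aged cells were mostly listed at 0 in all 3 aged stiff libraries. These were Pde6d, a prenyl-binding protein (57.4, 15.1 and 38.4 on soft gels), the RNA-binding protein Pcbp2 (9.39, 32.3 and 44.8), the galectin Lgals9 (23.8, 28.3 and 11.5), the defensin gene Defb13 (34.5, 53.4 and 133), and the olfactory receptor genes Olr244 (21.6, 22.9 and 15.3) and Olr1457 (37.3, 10.1 and 19.4). Stx4, a membrane fusion protein, was at 23.4, 11.5 and 83.9 on soft and 1.2, 0 and 0 on stiff gels. Adjusted p by limma was 0.0321 to 0.0336 for these 7 genes. Bsnd, Ascl3 and Atp6v0e2 were also called; they lie outside the rule for named genes and are named after their values were seen. Olfactory receptor genes had 150 members among the 1440 genes that were higher at an unadjusted p under 0.05, or 10.4%, against 5.26% of the genes tested.

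One list of 34 was called on aged gels, that of ribosomal proteins (1 of 77 rose, and 26 rose and 1 fell adjusted over the list alone; median 0.59 relative to all genes). Lists tied to mechanics and matrix were not called in aged cells by camera: collagens (adjusted p = 0.81), other matrix genes (0.812), integrins and adhesion (0.666), actin and myosin (0.708), YAP and TAZ targets (0.708), SRF targets (0.676) and mechanosensitive channels (0.825). OPC genes (0.912), microglia genes (0.666) and senescence genes (0.825) were not called either. Pdgfra was 9.23 ± 3.43 on soft and 9.29 ± 5.88 on stiff gels (SD, n = 3), Mbp 117 ± 77 and 30.9 ± 41.8, Mki67 6.82 ± 4.26 and 7.54 ± 5.48, and Piezo1, a stretch-activated channel (chromosome 19, 55305494 to 55367353), 19.2 ± 2.33 and 19.4 ± 12.1; limma called none of the 4 (adjusted p from 0.311 to 0.996). The count depended on single libraries, with 6 genes without aged soft replicate 1, 3 without aged soft replicate 3, 69 without aged stiff replicate 1 and 60 without aged stiff replicate 3. The lists called were then 2 without aged soft replicate 3 or without aged stiff replicate 2 or 3, and 3 without aged stiff replicate 1. Without the 3 broad libraries 117 genes were called, of which 4 were shared with the 12. The split by voom was 27 higher and 4 lower, and by quantile normalization 17 and 3. Array weights and a fit of only the groups compared each called 0 genes, no scaling 1, and thinned libraries 1 that was lower on soft gels. Of 9 named calls that of Dctn6 alone held whichever library was left out.

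In neonate cells, soft and stiff gels gave 0 genes past the threshold by limma, with 438 at an unadjusted p under 0.05 where chance gives 757. The spread of each gene was estimated over all groups, so these tests also depended on the spread of aged libraries. Counts of called genes at the 2 ages therefore do not show which age changed more. On read equivalents voom called 7, and fitting the model with library weights called 2. Camera called 5 lists, none of which held with an estimated correlation. Committed oligodendrocyte genes (camera, adjusted p = 0.00303, or adjusted p = 0.538 with an estimated correlation) and mature oligodendrocyte genes (adjusted p = 0.00376, or adjusted p = 0.538 with an estimated correlation) were lower on soft gels as lists. G2 and M phase genes were higher as a list (adjusted p = 0.0199, or adjusted p = 0.697 with an estimated correlation). Heat shock genes (adjusted p = 0.00376, or adjusted p = 0.538 with an estimated correlation) and lysosome genes (adjusted p = 0.04, or adjusted p = 0.538 with an estimated correlation) were lower. With the olfactory covariate camera no longer called mature oligodendrocyte (adjusted p = 0.102), heat shock (adjusted p = 0.0969) or lysosome genes (adjusted p = 0.196), the last also not without the broad libraries (adjusted p = 0.0762). As the broad libraries are aged, they bear on this comparison only through the genes tested, the scaling and the shared spread.

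None of the members of these 5 lists passed the test in neonate cells, over all genes or adjusted over the list alone. Mbp was 38.6 ± 40.3 scaled TPM on soft and 172 ± 60.7 on stiff gels (SD, n = 3), and Sirt2, a deacetylase of oligodendrocytes, 205 ± 219.5 and 422 ± 72. Nusap1, a spindle protein, was at 14.3, 20 and 16.4 on soft and 3.57, 0 and 0 on stiff gels. Pdgfra was 57.5 ± 6.44 and 31.9 ± 16.7, Mki67 9.12 ± 3.6 and 7.63 ± 4.57, and Piezo1 3.15 ± 1.96 and 2.08 ± 0.84 (SD, n = 3). YAP and TAZ targets (camera, adjusted p = 0.968), mechanosensitive channels (0.522) and SRF targets (0.0892) were not called. Without neonate soft replicate 1 the lists called numbered 1, and without neonate stiff replicate 3 limma called 1 gene.

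Whether stiffness acts differently at the 2 ages was tested as an interaction, the soft minus stiff difference in aged cells minus that in neonate cells. Dctn6 was the 1 gene called (limma, adjusted p = 0.0475), with 33 ± 5.92 scaled TPM on soft and 92.8 ± 83.1 on stiff gels in neonate cells (SD, n = 3), and listed at 0 in the aged stiff libraries. Ribosomal protein genes (0 of 77 members called, 7 adjusted over the list alone; camera, adjusted p = 7.42e-07, or adjusted p = 0.34 with an estimated correlation) and mature oligodendrocyte genes (0 of 20, 1 adjusted over the list alone; adjusted p = 0.00915, or adjusted p = 0.5 with an estimated correlation) had a more positive difference in aged cells. Immediate early genes had a more negative one (0 of 23, 0 adjusted over the list alone; adjusted p = 0.0467, or adjusted p = 0.36 with an estimated correlation). The median of all genes was 0.38. The call of the mature oligodendrocyte list was lost without the 3 broad libraries (camera, adjusted p = 0.0713) and after thinning (adjusted p = 0.209), and that of immediate early genes after thinning (adjusted p = 0.117) and with the olfactory covariate (adjusted p = 0.253). The call of Dctn6 was lost, leaving 0 genes, without aged soft replicate 1 or 3, without neonate soft replicate 1, 2 or 3, and without neonate stiff replicate 2. It was also lost without aged soft replicate 2, where 1 other gene was called with a negative interaction. Counts were 3, 2 and 6 without aged stiff replicate 1, 2 and 3, and 2 without neonate stiff replicate 3; 5 lists were called without neonate stiff replicate 2.

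**Figure D3:**
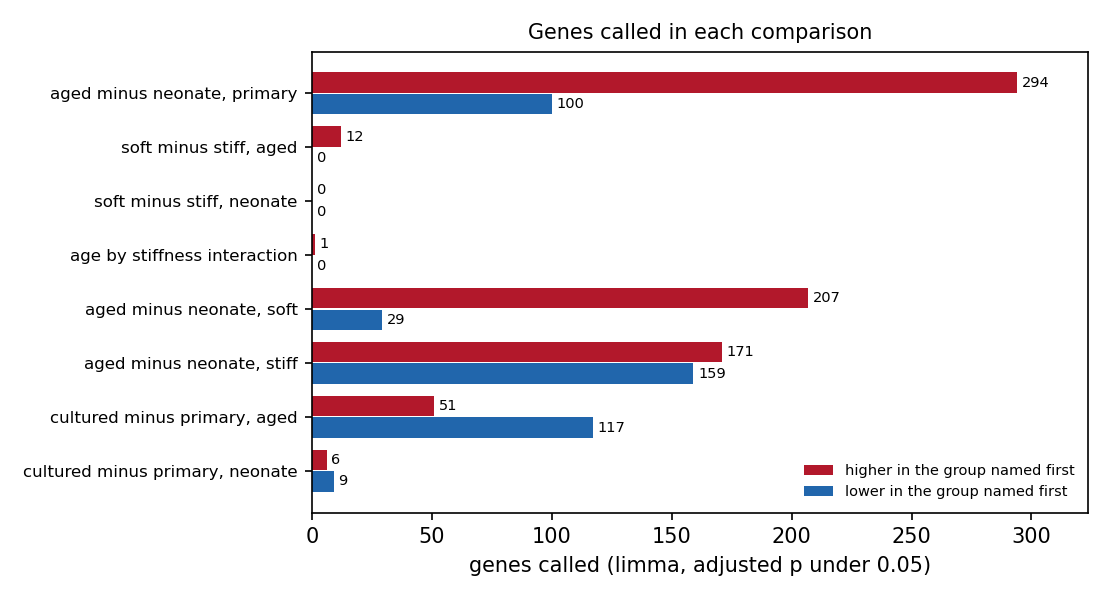
Bars give the number of genes called by limma at an adjusted p under 0.05, higher or lower in the group named first, for the 8 comparisons. The comparisons of soft with stiff gels called 12 and 0 genes, and those of age 236 to 394.

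If soft gels moved aged cells toward the neonate state, the soft minus stiff difference would follow the neonate minus aged difference of primary cells. Across 15144 genes, which are not independent replicates, Pearson's r was -0.05 and Spearman's rho -0.07 in aged cells, with a jackknife SE over libraries of 0.11. Leaving out 1 library at a time gave -0.09 to 0.03. In neonate cells r was -0.03 and rho -0.04. Among the 394 genes called with age in primary cells, r was -0.08. As sets, the 294 genes higher in aged primary cells had a median of 0.54 between soft and stiff gels in aged cells and the 100 lower ones 0.32, with 0.59 for all genes, and camera called neither set. The primary difference included 17 of 20 microglia genes, so it may partly reflect other cells among the aged ones. The aged gel difference was also open to a spread of reads. These values therefore cannot decide whether OPCs themselves moved toward a neonate state.

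On soft gels, aged cells had higher levels of microglia genes than neonate cells and lower levels of OPC genes. Cd68, a lysosomal protein of phagocytes (chromosome 10, 56268726 to 56270605), was at 234, 325 and 407 scaled TPM in aged libraries and listed at 0 in all neonate ones (limma, adjusted p = 1.31e-05). Adgre1, which encodes the macrophage antigen F4/80 (chromosome 9, 9431888 to 9585852), was at 686, 1404 and 829 against 0, 2.67 and 19 (limma, adjusted p = 1.31e-05), and Spp1, osteopontin (chromosome 14, 6673686 to 6679921), at 521, 579 and 937 against 0, 0 and 17.6 (limma, adjusted p = 0.000248). In all 236 genes were called, 207 higher and 29 lower in aged cells, and the median difference of all genes was 0.86.

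Microglia genes rose in 7 of 20 cases on soft gels (15 adjusted over the list alone; median 2.83 relative to all genes; camera, adjusted p = 8.89e-13, or adjusted p = 0.000859 with an estimated correlation). The chemokine Ccl4, Arhgdib, Ifi27, the fatty acid carrier Fabp4 and Tyrobp were further large rises. MHC genes rose in 3 of 18 cases (7 adjusted over the list alone; RT1-A2, B2m and Cd74; adjusted p = 1.7e-05, or adjusted p = 0.0135 with an estimated correlation). OPC genes fell in 3 of 19 cases (7 adjusted over the list alone; adjusted p = 6.83e-14, or adjusted p = 0.0091 with an estimated correlation). Ncan fell from 198 ± 11.1 in neonate to 19.3 ± 15.9 in aged cells (SD, n = 3; limma, log2 difference -3.60 ± 0.81 (SE), adjusted p = 0.0188), and Sox10, a lineage transcription factor (chromosome 7, 120393254 to 120403523), from 236 ± 74.6 to 30.8 ± 9.37 (SD, n = 3; limma, log2 difference -2.89 ± 0.75 (SE), adjusted p = 0.0439). Scd2, a fatty acid desaturase (chromosome 1, 264059374 to 264072433), fell from 317 ± 52 to 64.9 ± 30 (SD, n = 3; limma, adjusted p = 0.0193).

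Ribosomal protein genes were lower relative to all genes on soft gels (1 of 77 fell, Rplp1, also 1 adjusted over the list alone; camera, adjusted p = 6.83e-14, or adjusted p = 0.0116 with an estimated correlation), as were genes of oxidative phosphorylation (0 of 47 fell, 0 adjusted over the list alone; adjusted p = 4.07e-05, or adjusted p = 0.0251 with an estimated correlation). Cholesterol synthesis genes were lower in the preset test (0 of 25 fell, 2 adjusted over the list alone; adjusted p = 1.06e-05, or adjusted p = 0.0602 with an estimated correlation), and so were fatty acid genes (1 of 19 fell, Scd2; adjusted over the list alone 1 rose and 2 fell; adjusted p = 1.55e-05, or adjusted p = 0.0602 with an estimated correlation). The largest falls were those of Ndn, Mt3, Camk2n2, Hist1h4m, Dmrtb1, Phykpl, Ngfrap1 and Hist1h2ak, of which Mt3, Camk2n2, Dmrtb1, Phykpl and Ngfrap1 were listed at 0 in all 3 aged soft libraries. Camera called 18 lists, 5 of them with an estimated correlation (OPC, ribosomal protein, microglia, MHC and oxidative phosphorylation). Glycolysis genes were called lower (adjusted p = 0.00756, or adjusted p = 0.168 with an estimated correlation) although their median was 0.04, and genes of translation and ribosome assembly (adjusted p = 0.0249, or adjusted p = 0.21 with an estimated correlation) although it was 0.29, both with the median of all genes at 0.86. The glycolysis call was lost without the broad libraries, after thinning and with the olfactory covariate (camera, adjusted p = 0.156, 0.135 and 0.366), that of translation without the broad libraries (adjusted p = 0.228) and with the covariate (adjusted p = 0.339), and that of oxidative phosphorylation with the covariate (adjusted p = 0.0697). The 3 aged soft libraries covered 30.8% to 66.9% of olfactory receptor genes, and 21 of 796 tested olfactory receptor genes were called higher in aged soft cells. Without the 3 broad libraries 434 genes were called, 168 of them shared. The count was 117 with a pseudocount of 0.1, 145 with the olfactory covariate and 1133 by voom, and lower than 117 with only the groups compared. With quantile normalization the split was 186 higher and 103 lower. Leaving out 1 library gave 154 genes without aged soft replicate 1, and 105, 105 and 108 without neonate soft replicate 1, 2 and 3. Of 33 named calls 20 held whichever library was left out, and those of Apod, Bcan, Ctsz, Dmrtb1, Hist1h4m, Mt3, Ncan, Phykpl, Ppt1, Rplp1, Scd2, Sox10 and Tf did not.

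On stiff gels, aged cells had lower levels of ribosomal protein and OPC genes than neonate cells and higher levels of microglia genes. Of 77 ribosomal protein genes, 21 fell (40 adjusted over the list alone; median -2.45 relative to all genes; camera, adjusted p = 3.03e-35, or adjusted p = 0.00054 with an estimated correlation). Rpl27 fell from 1298 ± 357 scaled TPM in neonate to 185 ± 64 in aged cells (SD, n = 3; limma, log2 difference -2.82 ± 0.40 (SE), adjusted p = 0.000113), and Rps16 (chromosome 1, 85405499 to 85408444) was at 93.1, 125 and 82.2 in neonate cells and listed at 0 in aged ones (limma, adjusted p = 0.00015). Rpl39 and Rps13 also fell, though each has several loci in the files, so that their reads may be shared. In all 330 genes were called, 171 higher and 159 lower, with a median difference of all genes of 0.49.

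Microglia genes rose in 7 of 20 cases on stiff gels (10 adjusted over the list alone; adjusted p = 5.02e-11, or adjusted p = 0.00082 with an estimated correlation). Ccl3, a chemokine of macrophages (chromosome 10, 70869516 to 70871066), was at 537, 724 and 293 in aged and listed at 0 in neonate libraries (limma, adjusted p = 8.47e-07), and Lyz2, lysozyme (chromosome 7, 60335968 to 60341264), at 330.0, 228 and 505 against 8.8, 0 and 0 (limma, adjusted p = 0.000443). Other large rises were those of Trpt1, which overlaps Fermt3 on the other strand, the sodium pump regulator Fxyd2, the NADPH oxidase subunit Cyba, Cd14, Ddx39a and the immunoglobulin receptor Fcgr2a. Mechanosensitive channels were called higher as a list (2 of 18 rose, 3 adjusted over the list alone; adjusted p = 0.0127, or adjusted p = 0.302 with an estimated correlation). The risers were the cation channels Trpc6, at 22.5, 58.4 and 9.9 in aged and 0, 0 and 7.56 in neonate libraries (limma, adjusted p = 0.0325), and Trpv2, at 40, 3.41 and 29.8 and 1.02, 0 and 0 (limma, adjusted p = 0.045). Immediate early genes were also called higher (1 of 23 rose, Fos; adjusted over the list alone 8 rose and 1 fell; adjusted p = 0.0143, or adjusted p = 0.11 with an estimated correlation).

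OPC genes fell in 3 of 19 cases on stiff gels (9 adjusted over the list alone; adjusted p = 3.04e-09, or adjusted p = 0.0194 with an estimated correlation). Sox10 fell from 266 ± 75.2 in neonate to 13.6 ± 9.94 in aged cells (SD, n = 3; limma, log2 difference -4.50 ± 0.75 (SE), adjusted p = 0.00065), and Bcan, a proteoglycan, from 195, 177 and 140.0 to 5.26, 0 and 17.3 (limma, adjusted p = 0.000794). Fatty acid genes fell in 3 of 19 cases (10 adjusted over the list alone; Scd2, Fads1 and Tecr; adjusted p = 2.48e-08, or adjusted p = 0.0194 with an estimated correlation), with Scd2 going from 341 ± 98.1 to 39.1 ± 23.1 (SD, n = 3; limma, adjusted p = 0.000732). Oxidative phosphorylation genes fell in 2 of 47 cases (5 adjusted over the list alone; Atp5o and Atp5h, both listed at 0 in the aged stiff libraries; adjusted p = 2.7e-09, or adjusted p = 0.00276 with an estimated correlation). Gpi, a glycolytic isomerase (chromosome 1, 90063411 to 90091287), fell from 192 ± 57.8 to 15 ± 7.24 (SD, n = 3; limma, adjusted p = 0.000963), within a glycolysis list called lower (1 of 22 fell, 2 adjusted over the list alone; adjusted p = 0.0117, or adjusted p = 0.164 with an estimated correlation). That list was not called without the broad libraries (camera, adjusted p = 0.130) or with the olfactory covariate (adjusted p = 0.149).

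Mir93, Hist1h4m, Ngfrap1, the growth-inhibiting metallothionein Mt3, the transcription regulator Id3 and Dctn6 also fell on stiff gels, each listed at 0 in all 3 aged libraries. Mir93 lies within Mcm7, so its fall is not shown to be that of the microRNA. Camera called 20 lists, 5 of them with an estimated correlation (ribosomal protein, microglia, oxidative phosphorylation, OPC and fatty acid). With thinned libraries 153 genes were called, and a fit of only the groups compared called fewer still. Aged stiff replicate 3 had the fewest genes covered of all libraries, and without it 694 genes were called; without neonate stiff replicate 1, 2 or 3 the counts were 218, 185 and 197. The split was 172 higher and 50 lower with no scaling, 234 and 120 by voom, and 110 and 157 with quantile normalization. Of 40 named calls 25 held whichever library was left out, and those of Atp5h, Cd74, Ctsb, Fads1, Fos, Gfap, Kcns3, Lims2, Mir93, Mt3, Ncan, Nefm, Tecr, Trpc6 and Trpv2 did not.

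The 3 comparisons of age share no library, but 1 fit gave each gene the same spread in all of them. Genes of small spread could be called in several, so numbers expected of independent lists are a loose baseline. Between primary cells and soft gels, 73 genes were higher and 11 lower in aged cells in both, where independent lists would share 4.02 and 0.191. Between primary cells and stiff gels, 67 were higher and 28 lower in both, against 3.32 and 1.05, and 1 went in opposite directions. Soft and stiff gels shared 89 higher and 18 lower, against 2.34 and 0.304. Across all genes tested, which are not independent replicates, Pearson's r between the differences was 0.42, 0.38 and 0.45 in that order. Each aged group held 1 broad library. The 796 olfactory receptor genes that passed the filter had median differences of 1.44, 2.02 and 1.51 in primary cells, soft and stiff gels, which the filter itself may have raised. A shared spread of reads may therefore add to this agreement, and r was not computed without the broad libraries. In all 3 comparisons 51 genes were higher and 10 lower in aged cells, and 0 were mixed. The 51 included the microglia and macrophage genes C3, Cd68, Adgre1, Irf8, Laptm5 and Fcer1g, and the 10 included Ncan, Lims2, Ndn and Ngfrap1. Whether OPC and fatty acid genes were lower because other cells made up more of the aged libraries was not tested.

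**Figure D4:**
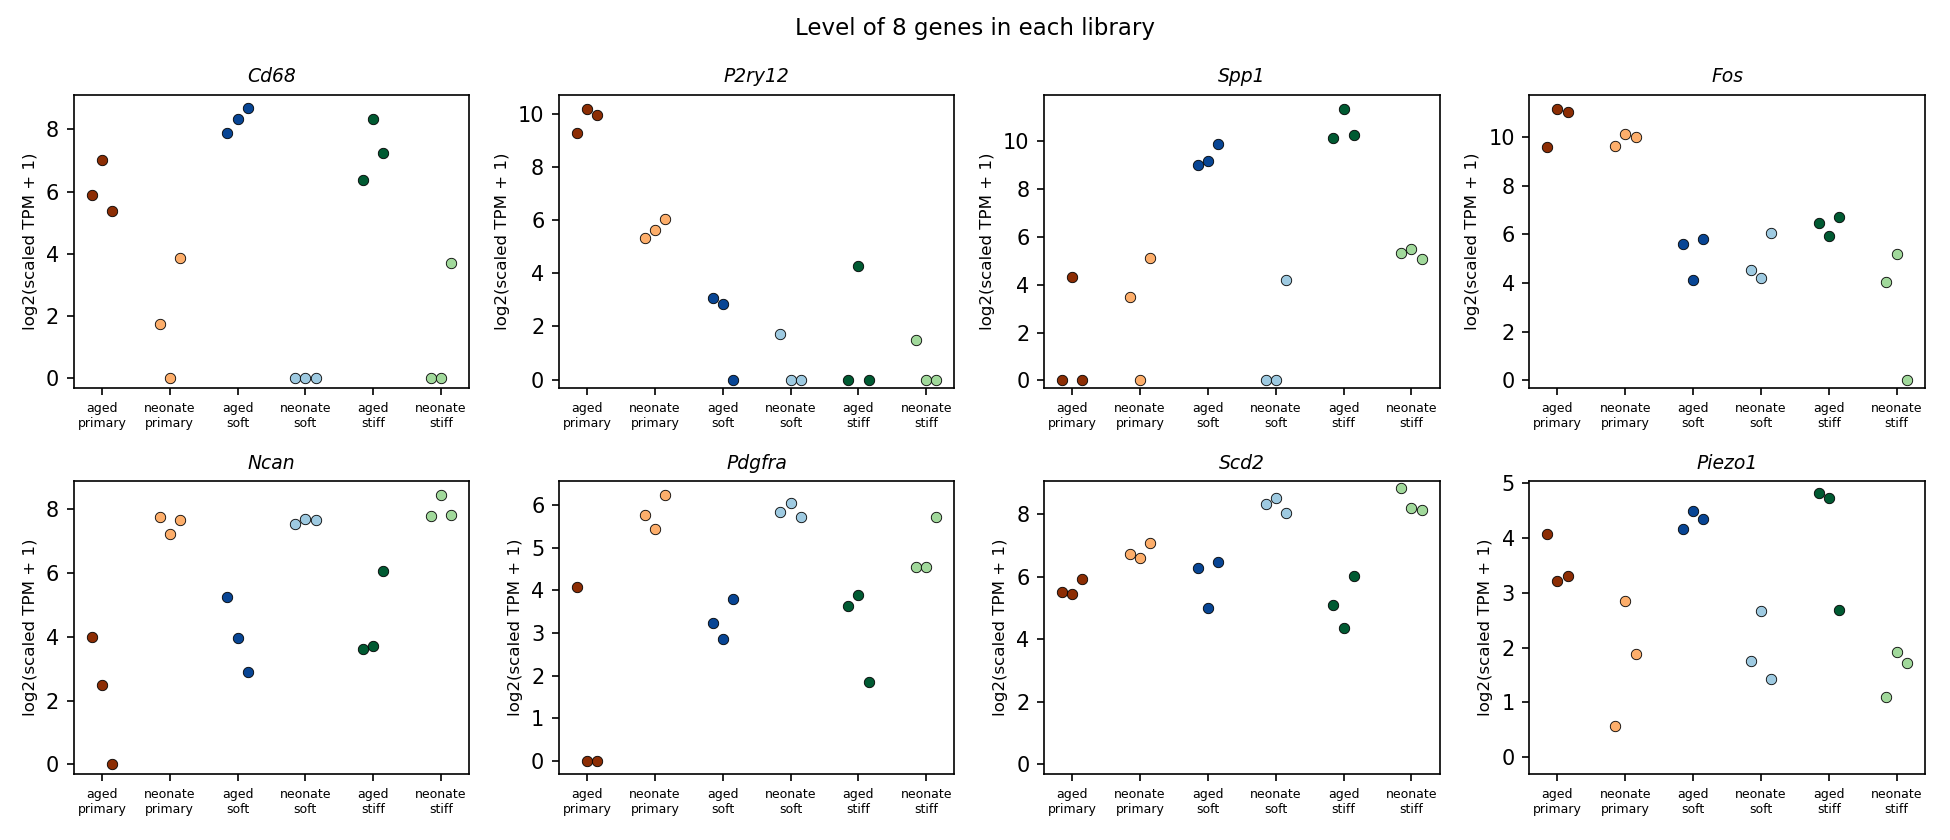
Each panel shows 1 gene, with each point the log2(scaled TPM + 1) of 1 library in the 6 groups, and points at 0 are libraries where the gene is listed at 0. Cd68 is higher in aged than in neonate libraries of each setting, Ncan lower, P2ry12 and Fos higher in primary than in cultured libraries of the same age, and Piezo1 higher on average in aged libraries without passing the limma test.

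Cultured aged cells differed from primary aged cells most in genes of microglia and of the immediate early response. At both ages culture and any preparation batch cannot be told apart, so these differences are not shown to be effects of culture. P2ry12, a purine receptor of resting microglia (chromosome 2, 149441601 to 149444548), fell from 621, 1164 and 978 scaled TPM in primary cells to 7.34, 6.1 and 0 on soft and 0, 18.2 and 0 on stiff gels (limma, adjusted p = 7.98e-06). Spp1 rose from 0, 19.3 and 0 to 521, 579 and 937 on soft and 1122, 2648 and 1223 on stiff gels (limma, adjusted p = 7.98e-06). Gpnmb, a glycoprotein of phagocytes (chromosome 4, 78694447 to 78715685), rose from 54 ± 50.3 to 1640 ± 624 on soft and 1385 ± 135 on stiff gels (SD, n = 3; limma, log2 difference 5.23 ± 0.57 (SE), adjusted p = 7.24e-06). In all 168 genes were called, 51 higher and 117 lower in culture.

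Microglia genes fell in 5 of 20 cases in cultured aged cells (10 adjusted over the list alone; camera, adjusted p = 2.67e-12, or adjusted p = 0.000859 with an estimated correlation), with Cx3cr1, the fractalkine receptor (chromosome 8, 128740756 to 128754514), going from 401, 389.8 and 586 to 49.7, 0 and 0 on soft and 41.4, 0 and 0 on stiff gels (limma, adjusted p = 0.00138). Immediate early genes fell in 6 of 23 cases (adjusted over the list alone 2 rose and 13 fell; adjusted p = 3.92e-09, or adjusted p = 0.00131 with an estimated correlation). Fos (chromosome 6, 109300433 to 109303299) fell from 1729 ± 835 to 39.6 ± 20.3 on soft and 83.8 ± 22.3 on stiff gels (SD, n = 3; limma, log2 difference -4.83 ± 0.74 (SE), adjusted p = 0.000488), and Egr1 also fell. OPC genes were higher as a list (1 of 19 rose, also 1 adjusted over the list alone; Olig1; adjusted p = 0.00123, or adjusted p = 0.186 with an estimated correlation), a call lost after thinning (camera, adjusted p = 0.0635). Fabp4, Edf1, the calcium-binding S100a4, the carboxylate transporter Slc13a3, Fxyd2 and Xpnpep1 were further large rises, and Fabp4 was listed at 0 in the primary libraries. Ttr, transthyretin, abundant in the choroid plexus, fell from 1871, 1428 and 6779 to 21.6, 0 and 14.4 and 21, 0 and 0 (limma, adjusted p = 7.98e-06). Hba1, a globin gene of red blood cells that overlaps Hba2, fell from 484, 2356 and 332 to 43.7, 0 and 0 on soft gels, and was listed at 0 on stiff ones (limma, adjusted p = 7.98e-06).

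Camera called 12 lists between cultured and primary aged cells, 2 of them with an estimated correlation (microglia and immediate early genes). Without aged primary replicate 2 the count fell to 43 genes and without aged primary replicate 3 to 80 genes. Without the 3 broad libraries it was 232, with 111 shared. Of 33 named calls 17 held whichever library was left out, and those of Bcas1, Ctss, Eif3b, Flna, Hspa1b, Ier2, Jund, Lims2, Ltc4s, Npc2, Olig1, Psap, Rps16, Rrm2, S100a4 and Slc13a3 did not.

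Cultured neonate cells had lower levels of immediate early and microglia genes and higher levels of metabolic genes than primary ones as lists, with 15 genes called, 6 higher and 9 lower. Fos was at 801, 1108 and 1031 scaled TPM in primary cells, 21.9, 17.3 and 66.3 on soft and 15.6, 35.5 and 0 on stiff gels (limma, adjusted p = 0.000172). Ttr fell from 561, 272 and 1209 to 0, 24 and 0 on soft gels and was listed at 0 on stiff ones (limma, adjusted p = 0.000172). Gpi rose from 17.1 ± 11.3 in primary cells to 182 ± 81 on soft and 192 ± 57.8 on stiff gels (SD, n = 3; limma, log2 difference 3.56 ± 0.55 (SE), adjusted p = 0.00198). Dlx1, a homeobox gene of interneurons (chromosome 3, 58164931 to 58169521), fell from 403 ± 26.8 to 23.8 ± 9.09 on soft and 54 ± 9.3 on stiff gels (SD, n = 3; limma, log2 difference -3.49 ± 0.65 (SE), adjusted p = 0.0152).

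Camera called 18 lists in neonate culture, 7 of them with an estimated correlation. Immediate early genes (2 of 23 fell, 5 adjusted over the list alone; adjusted p = 1.81e-10, or adjusted p = 0.0012 with an estimated correlation) and microglia genes (1 of 20 fell, P2ry12, 7 adjusted over the list alone; adjusted p = 2.02e-07, or adjusted p = 0.00429 with an estimated correlation) were lower. Glycolysis (1 of 22 rose, 6 adjusted over the list alone; adjusted p = 1.04e-09, or adjusted p = 0.00429 with an estimated correlation), oxidative phosphorylation (1 of 47 rose, 3 adjusted over the list alone; adjusted p = 1.28e-08, or adjusted p = 0.00429 with an estimated correlation), fatty acid (0 of 19 rose, 3 adjusted over the list alone; adjusted p = 2.3e-08, or adjusted p = 0.0192 with an estimated correlation), ribosomal protein (1 of 77 rose, 4 adjusted over the list alone; adjusted p = 4.44e-10, or adjusted p = 0.0192 with an estimated correlation) and committed oligodendrocyte genes (1 of 18 rose, Sirt2, 3 adjusted over the list alone; adjusted p = 5.93e-10, or adjusted p = 0.0297 with an estimated correlation) were higher. With no scaling the median of all genes was -0.47, and the medians of the ribosomal protein, glycolysis and oxidative phosphorylation lists turned negative, at -0.53, -0.14 and -0.20. YAP and TAZ targets were lower as a list (0 of 24 fell, 0 adjusted over the list alone; adjusted p = 0.049, or adjusted p = 0.459 with an estimated correlation), as were ependymal genes (1 of 6 fell, Dynlrb2, also 1 adjusted over the list alone; adjusted p = 0.0374, or adjusted p = 0.0894 with an estimated correlation). The call of YAP and TAZ targets was lost without the broad libraries (camera, adjusted p = 0.0821) and after thinning (adjusted p = 0.147). The broad libraries are aged, so they enter this comparison only through the genes tested, the scaling and the spread shared by all groups. Atp5o, Fdx1l, Rpl13 and the ribosomal RNA gene Rn5-8s also rose, and Hba1, Ccl3 and Btg2 fell; Rpl13 and Rn5-8s have several loci in the files. The split was 0 higher and 47 lower with no scaling and 2 and 8 with quantile normalization. Without neonate primary replicate 2 the count was 3 and without neonate primary replicate 3 it was 7. Of 15 named calls, those of Ccl3, Fos and Ttr held whichever library was left out.

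Lists of hypoxia, senescence, collagen, other matrix, adhesion, actomyosin and mural cell genes were not called in any of the 8 comparisons with all libraries and no covariate, where camera's adjusted p was 0.0641 or more. Under alternatives chosen after the data were seen, camera called collagens (adjusted p = 0.0200) and other matrix genes (adjusted p = 0.0423) higher in aged culture without the 3 broad libraries. With the olfactory receptor level as a covariate it called adhesion genes between ages on stiff gels (adjusted p = 0.0299) and actomyosin genes in neonate culture (adjusted p = 0.0439).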

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

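Results that differed between aged and neonate cells in the interaction test are collected here. Dctn6, a dynactin subunit, had an interaction of 6.12 on the log2 scale (limma, adjusted p = 0.0475): its soft minus stiff difference was larger in aged than in neonate cells. It was listed at 0 in all 3 aged stiff libraries, at 31.1 ± 1.46 scaled TPM in aged soft libraries, and at 33 ± 5.92 and 92.8 ± 83.1 on soft and stiff gels in neonate cells (SD, n = 3). The call was lost when any of 7 libraries was left out.

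The mature oligodendrocyte list differed between the ages (camera, adjusted p = 0.00915, or adjusted p = 0.5 with an estimated correlation), with a more positive difference in aged cells. The immediate early list differed in the other direction (camera, adjusted p = 0.0467, or adjusted p = 0.36 with an estimated correlation). Ribosomal protein genes had a more positive difference in aged cells (camera, adjusted p = 7.42e-07, or adjusted p = 0.34 with an estimated correlation), with mean levels of 4.94 in aged stiff and 6.39 in aged soft libraries. None of the 3 lists held with an estimated correlation. The call of the mature oligodendrocyte list was lost without the 3 broad libraries (camera, adjusted p = 0.0713) and after thinning (adjusted p = 0.209), and that of immediate early genes after thinning (adjusted p = 0.117) and with the olfactory covariate (adjusted p = 0.253).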

How the results depend on the processing

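Libraries of 3 per group, low depth and reads on genes of other tissues limit every count given here, in the order primary age, aged gel, neonate gel, interaction, soft age, stiff age, aged culture and neonate culture where named. A pseudocount of 0.1 gave 160 genes for primary age, 117 for soft age and 76 for aged culture, and 3 lists for the neonate gel and 1 for the interaction. Without a filter the interaction called 0, and a TPM filter of 5 left 6 genes for the aged gel. With no scaling the aged gel called 1, the interaction 0 and neonate culture 47 genes and 9 lists. Quantile normalization gave 20 genes for the aged gel, 2 lists for the neonate gel and 0 genes for the interaction. With voom primary age called 971, the aged gel 31, the neonate gel 7, the interaction 0, soft age 1133, aged culture 449 and neonate culture 72. Array weights gave 1165 for primary age, 0 genes and 2 lists for the aged gel, 2 for the neonate gel, 0 for the interaction, 441 for soft age and 200 for neonate culture. With only the groups compared, primary age called 102, the aged gel 0, the interaction 0, soft age 49, stiff age 22, aged culture 56 and neonate culture 36. A replicate block, which would pair libraries by number, left 0 genes for the interaction. Likeness between libraries of equal number was scored at 0.0172 to 0.0498 between neonate gels and 0.0163 to 0.118 between aged gels. These scores near 0 are not to be read as correlations of whole expression profiles. Libraries matched best with their own number in 3 cases for neonate gels and 2 for aged gels. The same held in 3 cases between aged and neonate primary cells, which come from different animals, so these matches did not settle whether libraries were paired. Without the 3 broad libraries there were 12 lists for primary age, and 117 genes for the aged gel, 6 for the interaction and 434 for soft age. Thinning gave 1 gene for the aged gel, lower on soft gels where the 12 were higher, 0 genes and 1 list for the interaction, 153 genes and 12 lists for stiff age and 4 lists for aged culture. The olfactory receptor level as a covariate gave 14 lists for primary age, 63 genes for the aged gel, 2 lists for the neonate gel, 0 genes for the interaction and 145 for soft age. With an estimated correlation camera called 5, 0, 0, 0, 5, 5, 2 and 7 lists. Leaving out 1 library gave 166 to 346 genes and 13 to 21 lists for primary age, 3 to 69 genes and 1 to 3 lists for the aged gel, 0 to 1 genes and 1 to 6 lists for the neonate gel, and 0 to 6 genes and 2 to 5 lists for the interaction. It gave 105 to 204 genes for soft age, 185 to 694 for stiff age, 43 to 231 for aged culture and 3 to 18 for neonate culture. Many named genes were chosen for large differences without overlap between groups, so reversals of their calls were unlikely from the start. Of 3480 alternatives to 176 named calls, 2843 gave the same call, 637 a weaker one and 0 a reversed one. The causes of these shifts were not tested.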

Other observations

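Piezo1, a channel opened by stretch of the membrane, was higher in aged than in neonate libraries in each setting, although limma called it in none. In primary cells the aged libraries were 11 ± 4.22 scaled TPM and the neonate ones 3.14 ± 2.9, with log2 differences of 1.76 in primary cells, 2.38 on soft and 2.49 on stiff gels. Over all settings the aged libraries were at 5.41 to 27.2 and the neonate ones at 0.483 to 6.24. The olfactory receptor genes tested, which glia do not use, had median differences between ages of 1.44, 2.02 and 1.51 in the same settings, and of 0, 1.99 and 0 without the 3 broad libraries. The filter on TPM may itself have raised these medians. Microglia genes were also higher in the aged libraries of these settings, with medians of 4.70, 3.69 and 3.02. Whether the difference of Piezo1 came from the spread of reads or from other cells among the aged ones was not tested. Piezo1 was among the genes named beforehand, and its comparison across settings was chosen after its values were seen. Piezo1 overlaps Ctu2 on the opposite strand.

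Broad detection in replicate 1 of each aged group was weighed with tests chosen only after it was seen. Greater depth did not explain it: after thinning the lowest of the 3 libraries had 8571 genes and the highest of the others 7697. At least 54.7% of olfactory receptor genes were covered in the 3 libraries and at most 39.2% in the others, which describes where the reads lay and largely restates the broad detection, so the cause was left open. Exonic bases made up 71.6% to 78.5% of aligned bases in the 3 libraries and 79.1% to 87.1% in the others. Aligned bases were estimated from coverage and FPKM, and whether they include reads away from annotated genes was not tested. This measure alone does not name a source of the reads, and whether genomic DNA was present was not tested.

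Microglia genes higher in aged cells were weighed with tests chosen only after the result was seen. Spread of reads was ruled against as the whole cause, as the lowest of the 3 medians without the broad libraries was 2.20. A lower share of progenitors raising all other cell types alike was weighed with the astrocyte, neuron, endothelial and mural lists. The smallest gap to microglia was 1.49, which met the prediction against it. Astrocyte genes were lower in aged cells (medians -0.734, -1.29 and -1.18), so not all lists rose alike. Endothelial and mural genes lay near the floor in neonate stiff libraries (means 0.302 and 0.745), where rises are compressed. A lower share of progenitors with unequal rises was therefore not excluded. Mature oligodendrocyte genes, left out of that test, were closer to microglia genes on soft gels (medians 2.28 and 3.69). Microglia or macrophages among the aged cells fit: a second list of 22 such genes, written when the microglia result was known, had a lowest median of 2.51. Aged cells that express these genes themselves could not be told from such cells here, with 2.51 open to both readings.

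Genes higher on soft than on stiff gels in aged cells were weighed with tests chosen only after the result was seen. Olfactory receptor genes made up 10.4% of those higher at an unadjusted p under 0.05 and 5.26% of those tested, which could not decide. Without the broad libraries they made up 13.8% of those called higher against 1.82% tested, which met the prediction for a spread of reads. Only olfactory genes at a TPM of at least 1 in at least 3 libraries were tested. Of the libraries left, aged soft replicates 2 and 3 covered the largest shares, 39.2% and 30.8%. The 13.8% therefore largely restates that coverage and decides nothing on the cause. Lower depth of the stiff libraries was not excluded: 75.9% remained higher after thinning, but the median of all genes went from 0.59 to 0.28 and the calls from 12 higher to 1 lower. With the olfactory receptor level as a covariate 63 genes were called; the bound of 6 set before this value was seen was met, but a condition added after the value was seen, that olfactory genes be no more frequent among calls than among tested genes, was not (19.0% against 5.26%), so it was not taken as deciding. Without the 3 broad libraries the calls were predicted to fall and rose from 12 to 117, and the cause was not tested.

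Regrouping libraries gave 10 splits for each comparison of 3 with 3, too few for a share under 0.05. Primary age called 394 genes against 1 at most in another split, with as many in 1 of 10, and 22 lists against 15 (1 of 10). Soft age called 236 against 0 (1 of 10) and 18 lists against 9 (1 of 10), and stiff age 330 against 3 (1 of 10) and 20 lists against 19 (1 of 10). The aged gel called 12 genes, equalled or passed by 5 of 10 splits with 226 at most, when aged soft replicates 1 and 2 and aged stiff replicate 1 were together, which points to a structure of the samples; its 1 list was equalled or passed in 8 of 10, with 12 at most. With the covariate its 63 genes stood against 47 (1 of 10). The neonate gel called 0 in all 10 of 10 splits (0 at most), and its 5 lists were reached in 4 of 10, with 11 at most.

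Larger sets of splits were possible for the other results. The interaction called 1 gene, reached in 14 of 100 splits with 3 at most, and 3 lists, reached in 40 of 100 with 12 at most. Aged culture called 168 genes, reached in 8 of 84 splits, with 3309 when the 3 broad libraries were together, a structure of the samples, and 12 lists, reached in 7 of 84 with 14 at most. Neonate culture called 15 genes (1 of 84, 2 at most) and 18 lists (1 of 84, 15 at most). The correlation of the aged gel with age in primary cells, -0.05, was equalled in size in 68 of 100 splits, with 0.187 at most.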
